A study of Mus musculus with 8 samples.

How the data were processed

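RNA was sequenced from 8 groups of cultured mouse peritoneal macrophages, 1 library each, from wild type and Chrna7 knockout C57BL/6 mice, given nicotine or vehicle and then LPS or vehicle. Per the labels' protocols, cells were plated and washed and treated the next day, RNA was extracted with a column kit, and libraries were made from poly(A) RNA with the TruSeq RNA Sample Prep Kit v2, which does not mark strand. Samples were put in groups by their titles and characteristics, and all 8 were used.

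The deposited table holds 1 FPKM value, a fragment count scaled by transcript length and by library size, per gene and library, made by the authors. The submitters' processing notes name CASAVA 1.8, HISAT2, Cufflinks and Cuffdiff and the build mm10, without role or order. The annotation, filters and any scaling between libraries are not given in the sources used here, and no fold changes or p-values of the authors were used. The table had 24341 lines. For 2 repeated symbols the line with the highest mean was kept, leaving 24339 genes, of which 7761 were at 0 in all libraries. Of the symbols, 27 read as dates, and no mitochondrially encoded gene was listed. None of 45 housekeeping and ribosomal genes was under 1 FPKM in all libraries, but Gapdh, a glycolytic gene that every cell uses, was listed at 1.34 to 8.90 FPKM, so a low or 0 value in this table can be a failed estimate. If FPKM was scaled by the total of each library, which is not known, a few very abundant genes can shift all others. Gene positions, lengths and GC content came from GENCODE release M21 on GRCm38, which holds 96.1% of the tested genes by symbol.

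FPKM values are not counts, so no count test was used. Differences were tested on log2(FPKM + 1) for the 10447 genes with a mean of at least 1 FPKM, with limma 3.58.1 in R 4.3.3, moderated with a trend on expression, and with Benjamini-Hochberg adjustment at 0.05. With 1 library per group, the average effects of LPS, genotype and nicotine came from an additive model with 4 residual degrees of freedom, whose spread is the departure from additivity. Any real interaction therefore enlarges this spread. Pairwise interactions came from a model with all 3 of them and 1 residual degree of freedom. Effects within 1 genotype or 1 treatment came from the same model and were chosen after the data were seen. Single pairs of libraries were compared without a test, as log2 ratios of FPKM + 1 for genes with at least 5 FPKM in either library, counting differences of at least 2-fold. The nicotine effect under LPS was compared between genotypes in the same way, for a mean of at least 5 FPKM. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for the rest.

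The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold (for the average effects also with the same sign in all 4 matched pairs), and the 10 highest and 10 lowest ratios of each pair contrast. It left out predicted genes, Rik genes and small RNA genes, and added list members with the largest and smallest changes and the genes of the question, Chrna7, Tnf, Il6, Il1b, Il10, Cxcl10, Nos2, Hes1, Hmox1, Jak2 and Stat3. The 30 lists were fixed with it. They cover cytokines, chemokines, interferon-stimulated genes, NF-kB feedback, effector enzymes, immediate early genes, Notch, JAK2-STAT3, antioxidant genes, cholesterol synthesis, lipid efflux, glycolysis, amino acid stress and heat shock. The others cover cell cycle, oxidative phosphorylation, ribosomal proteins, pattern recognition, antigen presentation, cholinergic and adrenergic receptors, aryl hydrocarbon receptor targets, sex-linked genes, Chrna7 neighbours and markers of 7 cell types. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, repeated with an estimated correlation and with fry. Some results of the rule are not reported here. In pair contrasts a list's median was placed among 10000 random lists of the same size matched on expression.

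The fits were tested on simulated data for the 10447 genes, with 100 genes changed 2-fold and 100 changed 4-fold. With a spread drawn from the fitted prior, the additive model recovered 92%, 87% and 93% of the 2-fold changes for LPS, genotype and nicotine, and 100%, 99% and 97% of the 4-fold ones, with 6.80%, 6.53% and 5% false calls. The interaction model then recovered 0% at either size. With the spread of the real fit it recovered 64%, 93% and 93% of 2-fold interactions (LPS by genotype, genotype by nicotine and LPS by nicotine), with 10.9%, 28.5% and 29.0% false calls. Both spreads came from the model with interactions, and no interaction was simulated for the average effects. The rates of the additive model therefore do not cover the real data, where interactions enlarge its spread.

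The depth was not given in counts. Steps between low values gave 9780000 to 16200000 fragments per library, on a scale that any scaling between libraries would alter. This estimate rests on 110 genes, its absolute scale has quartiles of 10400000 and 12400000 fragments, and only 14.0% to 16.7% of low genes lay at the inferred ratio, so no counting interval was drawn from it. Alternatives were pseudocounts of 0.1 and 5, a mean of at least 5 FPKM or no filter, quantile scaling and median centring, moderation without a trend, each factor alone, the 4 matched pairs as a block, single interactions, each library left out in turn, and at least 1 or 20 FPKM in pair contrasts.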

Results

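Gene expression was measured by RNA sequencing in peritoneal macrophages, the phagocytes of the abdominal cavity, from C57BL/6 mice that were wild type or lacked the α7 nicotinic acetylcholine receptor, encoded by Chrna7. The plated cells were given nicotine at 10 µM or vehicle for 15 min, and then lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor 4, at 100 ng/ml or vehicle for 4 h. The 2 genotypes, with and without nicotine and with and without LPS, made 8 groups of 1 library each, so no group had a replicate. Tests across genes therefore compared the 4 libraries with and the 4 libraries without each factor, with n = 4 in each arm, and took the spread from departures from additivity. The 4 libraries of an arm differed in the other factors, so they were not replicates of 1 condition. Labels did not say whether the 4 libraries of a genotype came from 1 preparation of cells or from several animals, so genotype and preparation cannot be told apart. For the same reason the libraries of a nicotine or LPS arm may not be independent preparations. The p-values measure only the spread between these libraries. Values were FPKM, fragment counts scaled by transcript length and by a measure of library size that the sources used here do not define. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

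Chrna7, the targeted gene (chromosome 7, 63098692 to 63212569, minus strand, GRCm38), was listed at 0 FPKM in all 8 libraries, those from wild type mice included. Its values therefore did not check the genotype labels. Low values in this table can be failed estimates, since Gapdh, a glycolytic gene that every cell uses, was listed at only 1.34 to 8.90 FPKM, against 3006 to 6998 FPKM for the elongation factor gene Eef1a1. The FPKM summed over genes was 413052 in wild type with vehicle, 529093 with nicotine, 795630 with LPS and 657052 with both, and 442307, 523764, 854016 and 627160 in the knockout libraries in the same order. The depth was not given in counts. An estimate from the steps between low values came to 9780000 to 16200000 fragments per library, on a scale that any scaling between libraries would alter. It rests on 110 genes, and only 14.0% to 16.7% of low genes lay at the inferred ratio, so it is rough. Lyz2, encoding lysozyme, had the highest FPKM in wild type with vehicle (32448) and with nicotine (23697). Saa3, an acute phase gene, had the highest value in wild type with LPS (46089) and in all 4 knockout libraries. Libraries given the same treatment resembled each other across genotypes, with a Pearson correlation across genes of 0.952 with vehicle, 0.969 with nicotine, 0.970 with LPS and 0.966 with both.

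LPS raised cytokine, chemokine and antiviral genes in both genotypes, with and without nicotine. Il6, encoding the cytokine interleukin 6 (chromosome 5, 30013114 to 30019981), was 534-fold higher with LPS (log2 change 9.06 ± 1.05, SE, limma adjusted p = 0.00324). The interferon-inducible chemokine Cxcl10 was 379-fold higher (8.57 ± 0.47, adjusted p = 0.000334), and the neutrophil attractants Cxcl1 and Cxcl2 were 267-fold and 103-fold higher. Il1b, encoding interleukin 1β, rose 236-fold, Ccl4 231-fold, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, 228-fold. The antiviral genes Ifit1 (260-fold), Rsad2 (248-fold), Oasl1 (169-fold), Cmpk2 (141-fold) and Isg15 (92.3-fold) rose alongside, each in all 4 matched pairs of libraries. Tnf rose 90.6-fold (adjusted p = 0.00164), the anti-inflammatory cytokine gene Il10 24.3-fold (adjusted p = 0.000268), the inducible nitric oxide synthase gene Nos2 26.8-fold (adjusted p = 0.0375) and the kinase gene Jak2 6.97-fold (adjusted p = 0.0113). Stat3 (log2 change 1.17 ± 0.44, adjusted p = 0.0842), Hmox1 (0.61 ± 0.35, adjusted p = 0.211, and -0.13 with quantile scaling) and the Notch target Hes1 (0.16 ± 0.18, adjusted p = 0.51) did not pass the test. The call of Nos2 ended without the wild type vehicle, wild type LPS, knockout vehicle, knockout nicotine or knockout LPS library (adjusted p = 0.107, 0.104, 0.12, 0.0522 and 0.0983).

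The genes that fell most with LPS included Tmem86a, a lysoplasmalogenase (14.1-fold lower, log2 change -3.81 ± 0.51, adjusted p = 0.00504), and the myeloid surface receptors Cd300lb (13.1-fold lower) and Cd300a (5.99-fold lower). Dhrs3, a retinal reductase, was 12.3-fold lower, the late endosomal GTPase Rab7b 10.5-fold lower (adjusted p = 0.00024), the amino acid transporter Slc43a2 8.82-fold lower and the transcription factor Nfic 7.40-fold lower. Pla2g15, a lysosomal phospholipase, was 6.89-fold lower, and Eepd1, Fblim1, Arl11 and Krt80 were between 6.36-fold and 6.97-fold lower. In total, 2824 of 10447 genes changed, 1648 upwards and 1176 downwards, and 957 of the former and 470 of the latter did so by at least 2-fold.

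By gene list, all 36 interferon-stimulated genes rose, with a median log2 change of 4.34 (36 adjusted over the list alone). Camera gave an adjusted p = 6.58e-23, and adjusted p = 0.512 with an estimated correlation. Among 22 inflammatory cytokines 20 rose (21 adjusted over the list alone), with Il6 and Il1b at the top, while Il18 (log2 change 1.89) and the growth factor gene Csf1 (2.21) had the smallest changes. The cytokine call had a camera adjusted p of 1.74e-10, and an adjusted p = 0.512 with an estimated correlation. Of 22 chemokines 13 rose (15 rose and 1 fell adjusted over the list alone). Of 26 genes of NF-kB feedback 24 rose (25 adjusted over the list alone), from Nfkbiz (4.67 ± 0.19) and Marcksl1 (4.55) down to Relb (1.14). Effector enzymes gave 13 risers and 1 faller of 19 (15 and 1 adjusted over the list alone). They were led by Ptgs2 and the cholesterol 25-hydroxylase gene Ch25h (5.73), with the protease gene Plau lower (-1.08). Immediate early genes gave 12 risers of 21 (16 risers and 1 faller adjusted over the list alone), led by the nuclear receptor gene Nr4a3 (3.71). Heat shock genes rose in 9 of 12 (9 adjusted over the list alone), with Hspa1b (2.47) and Hspa1a (2.30), which share reads with each other, at the top. Camera called these 5 lists upwards, with adjusted p between 3.64e-14 and 0.000267, and each had an adjusted p = 0.512 with an estimated correlation.

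Pattern recognition receptors went both ways, with 12 of 25 higher, among them the inflammasome sensor Nlrp3 (3.76) and Nod2 (2.87), and 3 lower, among them Tlr13 (-1.90). Of them 12 rose and 4 fell adjusted over the list alone. Of 20 genes of the JAK2-STAT3 pathway 9 rose (9 adjusted over the list alone), led by the feedback inhibitors Socs3 (3.54) and Cish (3.24). Antigen presentation genes rose in 14 of 18 (15 adjusted over the list alone), led by the peptide transporter Tap1 (2.71) and H2-Q7 (2.39). Ribosomal protein genes rose in 7 of 30 (6 adjusted over the list alone). With quantile scaling 6 and 0 members of those last 2 lists rose, and their medians moved from 0.84 to -0.06 and from 0.27 to -0.50. Mast cell markers rose in 7 of 10 and fell in 1 (7 and 1 adjusted over the list alone), and with quantile scaling rose in 3. The amino acid stress list rose in 4 of 20 (2 adjusted over the list alone), led by the chaperone gene Hspa5 (1.79), and with quantile scaling 2 rose and 1 fell. Camera called these 6 lists upwards, with adjusted p of 0.0161, 0.0161, 2.36e-05, 6.48e-05, 0.0189 and 0.0107 in that order. With an estimated correlation the adjusted p = 0.512 for 4 of them, adjusted p = 0.57 for JAK2-STAT3 and adjusted p = 0.59 for amino acid stress.

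Of the other lists, none was called by camera for LPS. The Notch list had 6 of 14 members higher, with Notch1 (1.72) and its ligand Dll1 (1.68) at the top, and 2 lower, with Hes6 (-1.21) lowest (6 and 3 adjusted over the list alone). Lipid efflux genes had 0 risers and 4 fallers of 20 (0 and 4 adjusted over the list alone), with Pparg among the lowest (-1.13), and 9 fallers with quantile scaling, where their median moved from -0.20 to -0.63. Antioxidant genes had 3 and 1 of 19 (3 and 1 adjusted over the list alone) and glycolysis genes 4 and 4 of 22 (5 and 6 adjusted over the list alone). With quantile scaling these last 2 lists gave 0 and 4, and 2 and 8, and their medians turned from 0.40 to -0.17 and from 0.24 to -0.24. None of 23 cholesterol synthesis genes passed (0 adjusted over the list alone), while 2 fell with quantile scaling and 1 with median centring. Markers of resident peritoneal macrophages gave 2 risers and 1 faller of 21 (2 and 1 adjusted over the list alone), and those of B cells 5 risers of 14 (5 adjusted over the list alone). With quantile scaling the B cell list had 2 risers, and the resident macrophage median turned from 0.12 to -0.13. Quantile scaling moved the median change of all genes from 0.02 to -0.08 and the share of calls that were higher from 58.4% to 44.5%. Without the wild type vehicle, wild type LPS, knockout vehicle or knockout LPS library the count was 1047, 1311, 803 or 944, with LPS as the only term it was 520, and with the 4 matched pairs as a block 1442. Of the 24 genes with the largest changes, 1 lost its call without each of these 4 libraries.

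Nicotine raised genes of the amino acid stress response and lowered interferon-inducible genes, whether or not the cells came from knockout mice. In fits of each genotype, chosen after the data were seen, 18 of 20 amino acid stress genes rose in wild type and 18 in knockout cells, and 32 and 29 of 36 interferon-stimulated genes fell (18, 18, 32 and 32 adjusted over the list alone). Gdf15, a stress-induced cytokine of the TGF-β family (chromosome 8, 70629393 to 70632456), was 55.8-fold higher (log2 change 5.80 ± 0.35, adjusted p = 0.00041). It went from 3.0 to 570 FPKM in wild type and from 1.75 to 163 FPKM in knockout macrophages without LPS. The ATF4 target and pseudokinase gene Trib3 was 29.2-fold higher, the leucine sensor gene Sesn2 23.6-fold, the glutathione-degrading enzyme gene Chac1 19.2-fold, and the asparagine synthetase gene Asns 14.9-fold. Impact, an inhibitor of the amino acid sensing kinase GCN2, was 18.5-fold higher, the amino acid transporter gene Slc38a2 14.6-fold (3.87 ± 0.13, adjusted p = 0.000226), and Ppp1r15a, a phosphatase subunit that reverses eIF2α phosphorylation, 13.7-fold. Samd11 (21.5-fold), Plcxd2 (15.0-fold), the folliculin partner gene Fnip2 (15.0-fold) and the cytokine gene Il3 (15.6-fold) completed the 12 largest rises. Hes1 (chromosome 16, 30064384 to 30067796) was 4.23-fold higher with nicotine (2.08 ± 0.18, adjusted p = 0.000498), and the haem oxygenase gene Hmox1 (chromosome 8, 75093621 to 75100589) 7.00-fold higher (2.81 ± 0.35, adjusted p = 0.00137). Il10 was 1.92-fold higher (adjusted p = 0.0166).

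The largest falls with nicotine were in Il27 (19.2-fold lower, log2 change -4.27 ± 1.28, adjusted p = 0.0325), the interferon-inducible GTPase gene Iigp1 (17.1-fold lower) and Il1b (17.0-fold lower, adjusted p = 0.019). The formyl peptide receptor gene Fpr1 was 15.0-fold lower, the fatty acid receptor gene Gpr84 13.2-fold lower, the high-affinity IgG receptor gene Fcgr1 9.32-fold lower and the chemokine gene Cxcl3 8.69-fold lower. Rin2, a regulator of endocytosis, Gbgt1, a glycosyltransferase gene, Emilin1, a matrix glycoprotein gene, Adap2, and the nuclear long noncoding RNA Neat1 were between 8.59-fold and 15.0-fold lower. Cxcl10 was 7.74-fold lower (-2.95 ± 0.47, adjusted p = 0.00322), Nos2 13.8-fold lower (adjusted p = 0.0491) and Jak2 2.90-fold lower (adjusted p = 0.0373). Averaged over libraries with and without LPS, Il6 (-1.44 ± 1.05, adjusted p = 0.295), Tnf (0.56 ± 0.62, adjusted p = 0.487) and Stat3 (-0.17 ± 0.44, adjusted p = 0.763) did not pass the test. Tnf turned to -0.18 without the wild type vehicle library, and Stat3 to 0.0015, 0.17 and 0.17 without the wild type LPS, wild type nicotine with LPS and knockout LPS library. The call of Nos2 ended without the wild type LPS, wild type nicotine with LPS, knockout nicotine, knockout LPS or knockout nicotine with LPS library (adjusted p = 0.122, 0.131, 0.0651, 0.123 and 0.131). That of Jak2 ended without the same 5 (adjusted p = 0.0862, 0.105, 0.0556, 0.106 and 0.106) or the knockout vehicle library (adjusted p = 0.0824). That of Il10 ended without the knockout vehicle (adjusted p = 0.0537) or nicotine with LPS library (adjusted p = 0.0544), and that of Il1b without the latter (adjusted p = 0.0567). Of the 24 genes with the largest changes, 3 lost the call without the knockout nicotine with LPS library and 2 without its wild type counterpart. A single gene lost it without each of wild type nicotine, wild type LPS, knockout vehicle and knockout LPS. In total 4842 of 10447 genes changed with nicotine, 2521 upwards and 2321 downwards, 1214 and 1049 of them by at least 2-fold. With nicotine as the only term the count was 2805.

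Among the lists, 18 of 20 amino acid stress genes rose (18 adjusted over the list alone, median 2.39), all but Hsp90b1 (0.11 ± 0.19, and -0.049 without the knockout vehicle library) and Xbp1 (-0.16 ± 0.23, and 0.0054 without the wild type LPS library). Heat shock genes rose in 10 of 12 (10 adjusted over the list alone), from Hsp90aa1 (2.35 ± 0.33) and Hspa1b (2.25) down to Dnaja1 (0.62, adjusted p = 0.164) and Hspa8 (0.49, adjusted p = 0.169), which did not pass. Ribosomal protein genes rose in 28 of 30 (28 adjusted over the list alone) by a median of 0.62, from Rpl23 (0.81 ± 0.12) down to Rps9 (0.39) and Rpl3 (0.21, adjusted p = 0.217). With quantile scaling 5 of them rose, with a median of 0.50. Interferon-stimulated genes fell in 26 of 36 (30 adjusted over the list alone, median -1.78), with Gbp5 (-3.10 ± 0.32) and Ifit3 (-2.83) lowest. Isg15 (1.02, adjusted p = 0.229) and Cd69 (0.50, adjusted p = 0.577, and -0.23 without the wild type nicotine library) did not pass. Genes of oxidative phosphorylation fell in 12 of 30 (12 adjusted over the list alone, median -0.18), with Ndufb3 (-0.90) and Sdhb (-0.80) lowest. Camera adjusted p was 5.91e-08, 0.000406, 3.01e-08, 4.37e-07 and 0.047 for these lists in that order. Each of these 5 calls was lost with an adjusted p = 0.848 with an estimated correlation.

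No other list was called by camera for nicotine. Cytokines gave 1 riser and 6 fallers of 22 (1 and 2 adjusted over the list alone), chemokines 0 and 6 of 22 (0 and 3), NF-kB feedback genes 2 and 9 of 26 (2 and 7) and effector enzymes 2 and 6 of 19 (2 and 5). With quantile scaling chemokines gave 2 and 7 and effector enzymes 1 and 4. Antioxidant genes had 8 of 19 members higher, led by Osgin1 (2.98 ± 0.21) and Hmox1, and 2 lower, Keap1 (-0.79) and G6pdx (-1.30), with the same counts adjusted over the list alone. Immediate early genes split into 5 higher, led by Fosl1 (2.39) and Klf4 (2.34), and 4 lower, among them Btg2 (-1.90), of 21 (5 and 4 adjusted over the list alone). In the Notch list Dtx1 (2.10 ± 0.23) and Hes1 were the highest of 3 risers, and Maml2 (-0.82) was the lowest of 2 fallers, of 14 (3 and 1 adjusted over the list alone), with 1 faller under quantile scaling. Pattern recognition receptors gave 2 risers and 9 fallers of 25 (2 and 9 adjusted over the list alone), with Ly96, the LPS co-receptor MD-2, higher (1.82 ± 0.19) and Tlr8 (-2.70) and Tlr3 (-2.31) lower. Glycolysis and hypoxia genes gave 5 risers, led by Vegfa (2.84), and 1 faller of 22 (3 and 0 adjusted over the list alone). Cholesterol synthesis genes gave 3, led by Insig1 (1.59), and 6 of 23 (2 and 4 adjusted over the list alone). The list of cholinergic and adrenergic genes had fewer than 3 tested members and was not tested.

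Markers of other cells moved with nicotine as well. Mast cell markers rose in 6 of 10 (6 adjusted over the list alone, median 1.11), led by Hpgds (2.06 ± 0.22) and the protease gene Mcpt4 (1.27 ± 0.13), while Tpsab1 (-0.26) and Mrgprb1 (-0.31) did not pass. T and NK cell markers rose in 4 of 9, led by Il7r (1.93) and Cd4 (1.03), and B cell markers in 4 of 14, led by Ebf1 (1.71) and Blk (1.37), with the same counts adjusted over the list alone. Granulocyte markers fell in 2 of 5 (2 adjusted over the list alone), with Csf3r lowest (-1.58). Of 21 resident macrophage markers 4 fell (2 adjusted over the list alone), among them the transcription factor Gata6 that sets their identity (-1.85 ± 0.20, adjusted p = 0.000903). Of 14 markers of small peritoneal macrophages and dendritic cells 3 rose, led by Xcr1 (2.47) and Irf4 (1.24), and 2 fell, Ccr2 (-1.83) among them, with the same counts adjusted over the list alone. Aryl hydrocarbon receptor targets gave 1 riser of 5, Tiparp (2.35), and 2 fallers (1 and 3 adjusted over the list alone), with 1 faller under quantile scaling. Of the mesothelial and fibroblast list only Dcn was tested, and it did not pass for nicotine (0.74, adjusted p = 0.218), LPS (1.01, adjusted p = 0.13) or genotype (-0.38, adjusted p = 0.824, and 0.18 without the wild type nicotine with LPS library).

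The nicotine change of inflammatory genes differed with and without LPS on the log2(FPKM + 1) scale. Part of this follows from genes near 0 FPKM without LPS, which nicotine could not lower there. The test of the difference, the LPS by nicotine interaction, gave a log2 difference of -8.11 for the noncoding gene U90926, which was at 0, 0, 0.44 and 0.19 FPKM in the libraries without LPS. Nos2 (-6.45 ± 0.25, adjusted p = 0.0143), Il27 (-6.44), Il1a (-6.18) and Ch25h (-6.08) were next among the genes named here. They were followed by the cytokine gene Osm (-5.67), Slfn4 (-5.12), Il6 (-5.12 ± 0.94, adjusted p = 0.0273), the endothelial lipase gene Lipg (-5.11) and AA467197 (-4.66). Il1bos (-5.11) lies antisense to Il1b, and reads of the pair cannot be told apart in a library that does not record strand. In the other direction, genes that were lower with LPS when nicotine was absent, and less so or not at all when it was present, included the stress gene Sesn1 (4.20 ± 0.20, adjusted p = 0.0143), Ypel3 (4.06), the circadian transcription factor gene Dbp (3.88) and Engase (4.29). They also included Abcd2 (3.85), Susd3 (3.85), Rgs2 (3.64), the MYC antagonist Mxd4 (3.37), Nfam1 (3.30), the potassium channel gene Kcnj2 (3.29) and the inhibitory receptor gene Lair1 (3.29). Eif3j1 (4.4) was listed at 0.108 FPKM in 6 libraries and above 22 in both with nicotine and LPS, and is uncertain, since it shares reads with a near-identical copy.

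In total the interaction passed for 3219 genes, 1339 with a positive and 1880 with a negative difference. Of the negative ones 371 were under 5 FPKM in both vehicle libraries, and of the positive ones 893 were under 5 FPKM in both libraries given LPS alone, where little was left to lower. The difference was negative in 18 of 22 inflammatory cytokines (20 adjusted over the list alone), 14 of 22 chemokines (15) and 19 of 36 interferon-stimulated genes (22, and 1 positive). So it was in 18 of 26 NF-kB feedback genes (22), 12 of 19 effector enzymes (14, and 1 positive) and 11 of 20 amino acid stress genes (13, and 1 positive), where the figures in parentheses are adjusted over the list alone. Among members not under 5 FPKM in both vehicle libraries it was negative in 8 of 9 cytokines, 10 of 18 chemokines, 15 of 31 interferon-stimulated genes, 17 of 25 NF-kB feedback genes, 9 of 16 effector enzymes and 8 of 14 amino acid stress genes. With quantile scaling it was negative in 9 NF-kB feedback genes (median from -1.24 to -0.62), 8 chemokines with 1 positive, 7 amino acid stress genes, and 9 effector enzymes with 2 positive. Stat3 (-2.07 ± 0.21, adjusted p = 0.0161), Jak2 (-2.14, adjusted p = 0.0329), Tnf (-2.51, adjusted p = 0.0435) and Hmox1 (-0.92, adjusted p = 0.0461) passed. Il1b (-4.12 ± 1.47, adjusted p = 0.098), Cxcl10 (-1.54, adjusted p = 0.0999), Il10 (-0.18, adjusted p = 0.655) and Hes1 (-0.09, adjusted p = 0.764) did not. With a pseudocount of 5 the last pair turned to 0.42 and 0.014. This model had 1 residual degree of freedom, and without the filter on low FPKM 0 genes passed. In simulated data with the spread of the real fit, 29.0% of the calls of this test were false. With a spread drawn from the fitted prior it recovered 0% of the changes. Quantile scaling moved the median difference over all genes from -0.11 to -0.01 and the share of positive calls from 41.6% to 52.9%.

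Effects of nicotine with and without LPS came from the same model as the interaction and were chosen after the data were seen. Without LPS, nicotine raised Osm 14.4-fold (3.85 ± 0.21, limma adjusted p = 0.00305), Il1a 8.40-fold, Cxcl2 17.9-fold and Tnf 3.52-fold (1.81 ± 0.43, adjusted p = 0.0242). Of 22 cytokines 7 were then higher and 1 lower (7 and 1 adjusted over the list alone). With LPS, 19 of the 22 cytokines were lower with nicotine (19 adjusted over the list alone). Of the list 1, Il10, was higher (0.85 ± 0.21, adjusted p = 0.0257). Il27 was then 179-fold lower, Nos2 129-fold lower (-7.01 ± 0.18, adjusted p = 0.00198), Il1b 71.1-fold lower (-6.15 ± 1.04, adjusted p = 0.01), Il6 16.0-fold lower (-4.00 ± 0.67, adjusted p = 0.00978) and Cxcl10 13.2-fold lower (adjusted p = 0.00355). Tnf (-0.69 ± 0.43, adjusted p = 0.227) did not pass. Interferon-stimulated genes were lower in 32 of 36 and chemokines in 17 of 22 with LPS, where none was higher. Without LPS 17 interferon-stimulated genes were lower and 3 higher, and 3 chemokines lower and 5 higher. Adjusted over the list alone 33 and 17 were lower with LPS, and without it 17 were lower and 3 higher, and 3 lower and 4 higher. Hes1 was 4.37-fold higher with nicotine without LPS and 4.10-fold higher with it. Amino acid stress genes rose in 19 of 20 without and in 17 of 20 with LPS (19 and 17 adjusted over the list alone), where Xbp1 fell (-0.63, adjusted p = 0.0169). With quantile scaling the value of Tnf with LPS turned to 0.058, and that of Xbp1 without LPS to -0.15.

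Within each genotype, nicotine before LPS was compared with LPS alone. This contrast holds the effect that nicotine had by itself as well as any change of the LPS response. These are ratios of 1 library to another, with no replicate check. In wild type macrophages Il6 went from 7857 to 242 FPKM (log2 ratio -5.02), Il1b from 19504 to 63.2 (-8.25), Nos2 from 164 to 1.56 (-6.01), Cxcl10 from 7244 to 509 (-3.83) and Tnf from 4806 to 3118 (-0.62). In knockout macrophages Il6 went from 10058 to 1274 FPKM (-2.98), Il1b from 17894 to 1076 (-4.05), Nos2 from 1189 to 3.61 (-8.01), Cxcl10 from 10567 to 861 (-3.62) and Tnf from 4794 to 2821 (-0.76). Il10 went from 29.0 to 48.7 FPKM in wild type and from 52.8 to 104 FPKM in knockout cells. Hes1 went from 1.62 to 11.8 FPKM in wild type (2.30) and from 1.01 to 5.87 FPKM in knockout cells (1.77), and Hmox1 from 796 to 6180 (2.96) and from 872 to 2916 (1.74). Jak2 was lower with nicotine in both (-2.80 and -2.41), as was Stat3 (-1.21 and -1.20).

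**Figure D1:**
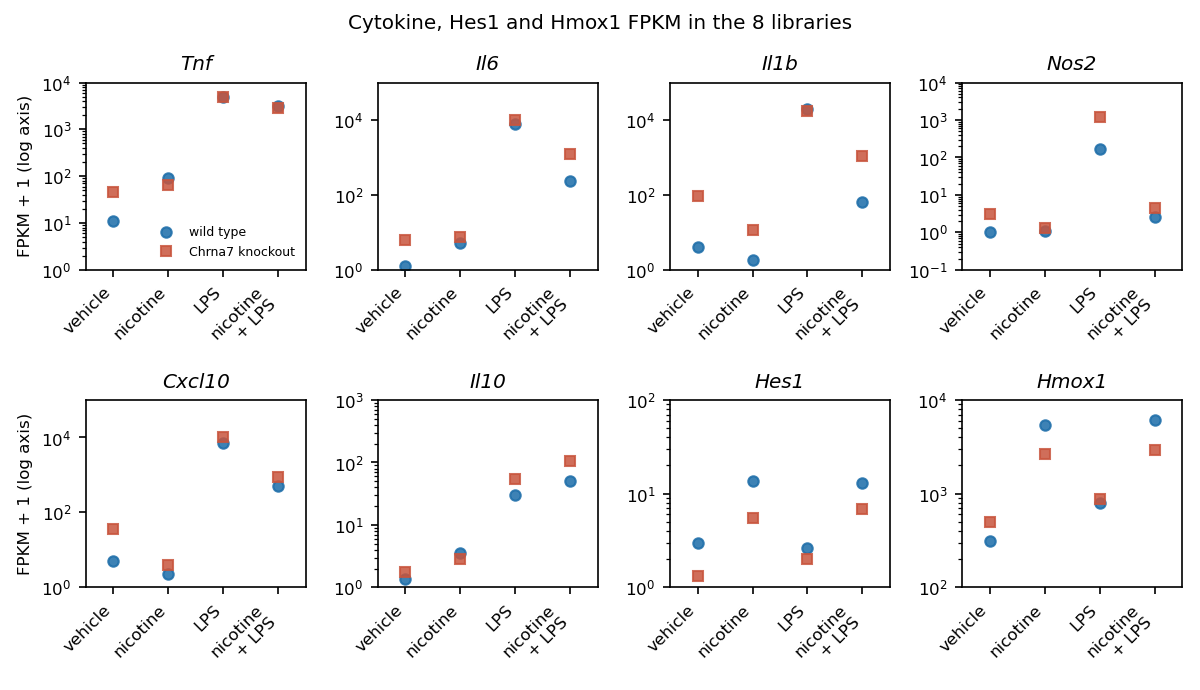
FPKM + 1 on a log axis for 8 genes in the 8 libraries, by treatment, with circles for wild type and squares for Chrna7 knockout macrophages; each point is 1 library. Il6, Il1b, Nos2 and Cxcl10 lie lower with nicotine and LPS than with LPS alone in both genotypes, and Hes1 and Hmox1 lie higher with nicotine.

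The largest ratios of this contrast in wild type cells included rises in the chemokine receptor gene Cxcr4 (48.4-fold), Samd11 (40.7-fold), Gdf15 (27.8-fold), Fnip2 (27.2-fold), Impact (26.8-fold), Il3 (24.9-fold) and the folliculin gene Flcn (24.8-fold). The largest falls included Csf2, encoding GM-CSF (376-fold lower), Il27 (352-fold), Il1b (304-fold), U90926 (190-fold) and Cxcl3 (109-fold). In knockout cells the largest rises included Sesn2 (45.7-fold), Gdf15 (41.1-fold), Il3 (31.1-fold), Samd11 (26.0-fold) and Trib3 (25-fold). The largest falls there included U90926 (482-fold lower), Nos2 (258-fold), Il27 (91.0-fold), Ch25h (89.3-fold) and the purine phosphorylase gene Pnp2 (41.9-fold). At least 2-fold differences were counted in 2815 of 7703 genes in wild type (1314 higher and 1501 lower) and 2476 of 7683 in knockout cells (1075 higher and 1401 lower). The median cytokine was lower by a log2 ratio of -3.69 in wild type and -2.76 in knockout cells, and the median interferon-stimulated gene by -3.14 and -1.96. Each of these 4 medians lay at percentile 0 of 10000 random lists of the same size matched on expression, and the amino acid stress list (1.47 and 2.08) at percentile 100 in both genotypes.

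Without LPS, nicotine gave at least 2-fold differences in 2581 of 7970 genes in wild type and 2444 of 7905 in knockout cells. Gdf15 was 143-fold higher in wild type and 59.5-fold higher in knockout cells, Trib3 39.5-fold and 55.6-fold, and the calcitonin receptor partner gene Ramp3 25.5-fold and 24.4-fold. The cystine transporter gene Slc7a11 was 56.1-fold and Cxcl2 45.5-fold higher in wild type cells. Neat1 was 25.9-fold lower in wild type and 15.7-fold lower in knockout cells, Engase 21.5-fold and Emilin1 19.1-fold lower in wild type, and Iigp1 15.9-fold and Gbp5 13.1-fold lower in knockout cells. LPS alone gave such differences in 3190 of 8124 genes in wild type and 2690 of 8013 in knockout cells, among them Il6 (6216-fold higher in wild type and 1593-fold in knockout) and Ptgs2 (2369-fold and 304-fold). Engase (55.4-fold), Tmem86a (47.2-fold) and Cxcr4 (38.8-fold) were among the genes with the largest falls in wild type, and Tmem86a (24.2-fold), Cd300lb (22.3-fold) and Slc43a2 (20.8-fold) among those in knockout cells.

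Whether the effect of nicotine needed the α7 receptor is the question that the knockout addresses. No gene passed the test of a different nicotine effect in the genotypes (limma, 0 genes, smallest adjusted p = 0.74, 634 genes at an unadjusted p under 0.05). The nicotine effect in knockout minus that in wild type cells was -0.33 ± 0.22 for Hes1 (adjusted p = 0.769), and 0.23 with a pseudocount of 0.1. For Hmox1 it differed by -1.46 ± 0.23 (adjusted p = 0.74), for Tnf by -1.33 ± 0.60 (adjusted p = 0.74) and for Nos2 by -1.65 ± 0.25 (adjusted p = 0.74). For Il6 it differed by 0.11 ± 0.94 (adjusted p = 0.981), for Il1b by 1.17 ± 1.47 (adjusted p = 0.863), for Il10 by -0.23 ± 0.29 (adjusted p = 0.862) and for Cxcl10 by -0.87 ± 0.55 (adjusted p = 0.754). Il6 turned to -0.63 with a pseudocount of 0.1 and Il10 to 0.0070 with 5. Effects within each genotype came from the same model of all 8 libraries and were chosen after the data were seen. In it nicotine changed 5727 genes in wild type and 5338 in knockout cells. Of these, 4568 were shared, 4566 of them with the same sign. Both tests use the same spread of each gene, with 1 residual degree of freedom, so the shared calls are not independent. Tests of effects within a genotype were not simulated. Across all 10447 genes, which are not independent replicates, the nicotine changes of the genotypes had a Pearson correlation of 0.930, a Spearman correlation of 0.923 and a slope of 0.876 for knockout on wild type. A test with 1 residual degree of freedom recovered 0% of simulated interactions when their spread was drawn from the fitted prior, and 93% of 2-fold ones with the spread of the real fit, so the 0 calls do not show that the genotypes responded alike.

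**Figure D2:**
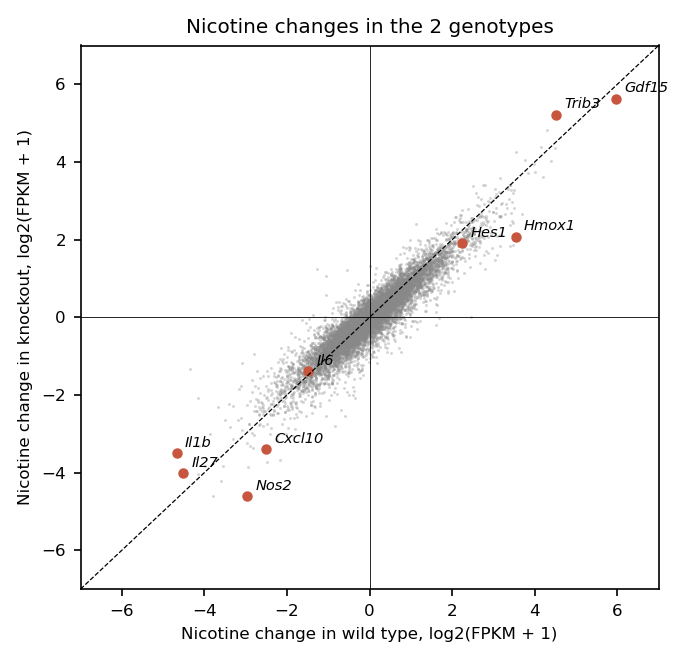
Nicotine change of each of 10447 genes in knockout (vertical axis) against wild type macrophages (horizontal axis), on the log2(FPKM + 1) scale, averaged over libraries with and without LPS, with 9 genes named and the line of equal change dashed. Points follow the diagonal, with a correlation across genes of 0.930.

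Under LPS, the nicotine effect of wild type minus that of knockout cells, a difference of 4 single libraries with no test, was at least 2-fold in 486 of 7199 genes, 240 positive and 246 negative. Nicotine lowered Csf2 by more in wild type (log2 difference -5.93), where LPS alone had raised it to 604 FPKM against 24.1 FPKM in knockout cells. The difference was also negative for Cxcl3 (-4.50), Il1b (-4.19), the chemokine gene Ccl17 (-3.17), the siderophore-binding lipocalin gene Lcn2 (-3.02), Pdgfb (-2.87), Shisa3 (-2.73), Ifit3b (-2.73), Plet1 (-2.58), AW112010 (-2.76) and Il6 (-2.04), and positive for Nos2 (2.0), which fell further in knockout cells. Cd244 (2.75), the glutamate transporter gene Slc1a2 (2.67), Pde7b (2.49), the complement receptor gene C3ar1 (2.31), Mospd4 (2.29), Ccl7 (2.22), Apoc1 (2.11), Cd5l (2.07), Cxcl11 (2.07) and Aldh1b1 (2.06) were the most positive. Interferon-stimulated genes had a median of -1.25, with 21 of 36 lower in wild type by at least 2-fold and 1 higher, and cytokines a median of -1.01, with 11 of 22 lower and 2 higher, both at percentile 0 of random lists. Cholesterol synthesis genes had a median of -0.68 (percentile 0), and resident macrophage markers 0.55 with 7 of 21 higher and 2 lower (percentile 100). Hes1 differed by 0.52 and Hmox1 by 1.21. With a pseudocount of 5 or an FPKM of at least 20 the count of 486 became 292 or 294.

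The knockout libraries differed from wild type by a smaller number of genes, several of them markers of macrophage state. Vsig4, the complement receptor of resident macrophages (chromosome X, 96247203 to 96293438), was 20.7-fold lower in knockout cells (log2 change -4.37 ± 0.29, adjusted p = 0.00326), with 165 FPKM in wild type and 7.93 FPKM in knockout cells given vehicle. The C-type lectin genes Cd209a (14.4-fold lower) and Cd209b (4.84-fold lower), prostacyclin synthase Ptgis (8.0-fold), the ribonuclease gene Ear2 (7.36-fold), Apoc4 (6.12-fold) and the coagulation genes F5 (5.06-fold) and F13a1 (4.17-fold) were lower as well. So were Mmp27, Mamdc2, Emp1 and the lysosomal protease gene Lgmn, between 3.89-fold and 4.09-fold, and Apoe (3.84-fold lower, -1.94 ± 0.12, adjusted p = 0.00311), encoding a lipid carrier. Genes that were higher included the surface antigen genes Ly6i (30.0-fold, 4.90 ± 0.33, adjusted p = 0.00326) and Ly6c2 (14.5-fold), Wfdc21 (18.2-fold), the protease inhibitor gene Cst7 (8.24-fold), Serf1 (7.35-fold), Smpdl3b (7.23-fold) and Clec4n, the fungal receptor dectin-2 (5.08-fold, 2.35 ± 0.14, adjusted p = 0.00311). H2-M2 (4.99-fold), Gpr141 (4.91-fold), the anthrax toxin receptor gene Antxr1 (4.70-fold), the guanylate-binding protein gene Gbp6 (4.55-fold) and complement C3 (4.53-fold) followed. The Ly6, Cd209, Ear and Serf1 genes have related genes with which reads may be shared, which was not checked here.

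**Figure D3:**
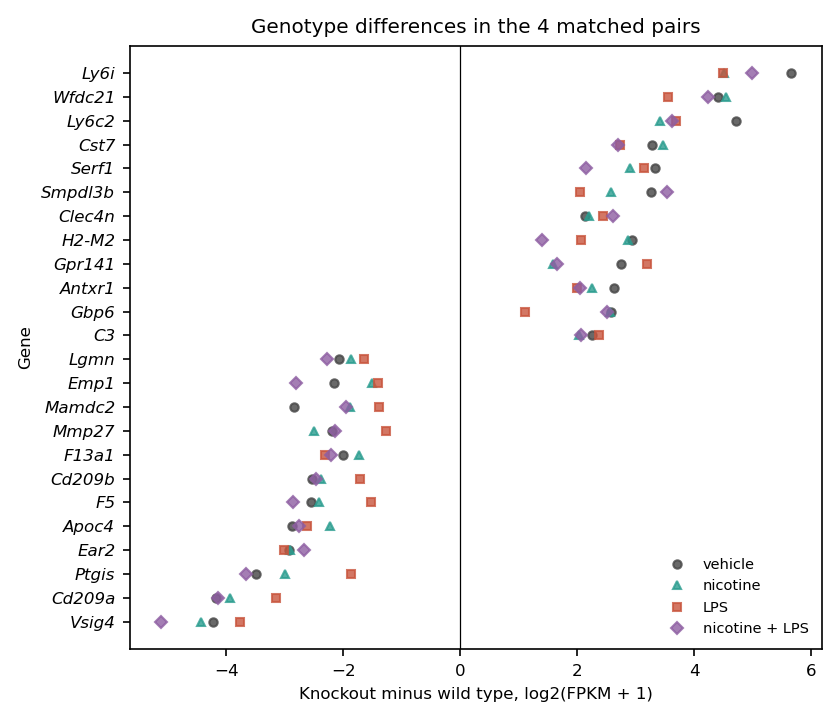
Knockout minus wild type difference in log2(FPKM + 1) for the 12 genes with the largest rise and the 12 with the largest fall by genotype, with 1 marker for each of the 4 matched pairs of libraries. All 4 pairs lie on the same side of 0 for each gene, from Vsig4 to Ly6i.

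In total 115 of 10447 genes passed for genotype, 72 higher and 43 lower in knockout, 64 and 41 of them by at least 2-fold. Hes1 was lower in knockout by -0.94 ± 0.18 but did not pass (adjusted p = 0.0848), and neither did Il6 (1.39 ± 1.05, adjusted p = 0.675), Il1b (2.78 ± 1.06, adjusted p = 0.344), Tnf (0.36 ± 0.62, adjusted p = 0.891), Nos2 (1.42 ± 1.29, adjusted p = 0.743), Cxcl10 (1.22, adjusted p = 0.35), Il10 (0.51, adjusted p = 0.453), Hmox1 (-0.33, adjusted p = 0.797), Jak2 (0.23, adjusted p = 0.914) or Stat3 (0.47, adjusted p = 0.75). Without the wild type vehicle library Tnf turned to -0.38 and Jak2 to -0.28. The count was 26, 36, 171 and 24 without the wild type vehicle, nicotine, LPS and nicotine with LPS library, and 21, 13, 17 and 37 without the knockout library of the same treatments. Of the 24 genes with the largest changes named above, 11, 9, 1 and 12, and 12, 15, 13 and 8, lost the call without these libraries in the same order. The count was 55 with no filter on FPKM, 19 with genotype as the only term and 798 with the matched pairs as a block. Those blocks take the LPS by nicotine difference, past its test in 3219 genes, out of the spread. The additive model leaves that difference in, so a gene that did not pass here may still differ by genotype.

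Interferon-stimulated genes had a median genotype change of 1.36, and 0 of 36 passed over all genes while 17 rose adjusted over the list alone. Camera gave an adjusted p = 3.98e-17, and adjusted p = 0.329 with an estimated correlation. Irf7 (2.27 ± 0.65, adjusted p = 0.217) and Zbp1 (2.24) had the largest values. Chemokines gave 3 risers of 22 (3 adjusted over the list alone, camera adjusted p = 5.93e-06, and adjusted p = 0.381 with an estimated correlation). Lipid efflux genes gave 6 fallers of 20 (8 adjusted over the list alone), with Apoe and Apoc1 (-2.04, adjusted p = 0.057) lowest (camera adjusted p = 5.93e-06, and adjusted p = 0.329 with an estimated correlation). Glycolysis genes gave 4 risers of 22 (8 adjusted over the list alone), led by the lactate exporter gene Slc16a3 (1.44 ± 0.18, adjusted p = 0.0206; camera adjusted p = 3.23e-07, and adjusted p = 0.329 with an estimated correlation), and 2 risers with quantile scaling. Effector enzymes gave 1 riser of 19, the gelatinase gene Mmp9 (2.13 ± 0.24, adjusted p = 0.0172; 3 adjusted over the list alone, camera adjusted p = 0.00692, and adjusted p = 0.614 with an estimated correlation). Of the resident macrophage markers 0 rose and 3 of 21 fell (2 and 8 adjusted over the list alone), Vsig4, F5 and Gata6 (-1.24, adjusted p = 0.0458, named after its value was seen). Timd4 (1.45, adjusted p = 0.211) and Saa3 (1.59, adjusted p = 0.212) did not pass. Camera gave an adjusted p = 0.00396 downwards, and adjusted p = 0.381 with an estimated correlation.

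Among the remaining lists, camera called 5 upwards: cytokines (median 0.65, 0 past and 0 adjusted over the list alone), NF-kB feedback (0.18, 0 past and 0 adjusted over the list alone), cell cycle (0.38, 0 past and 4 adjusted over the list alone), oxidative phosphorylation (0.34, 0 past and 2 adjusted over the list alone) and antigen presentation (0.38, 0 past and 7 adjusted over the list alone). Their adjusted p was 0.0249, 0.0392, 0.000215, 8.56e-10 and 0.00396, and adjusted p = 0.697, 0.723, 0.381, 0.329 and 0.366 with an estimated correlation. Camera called the aryl hydrocarbon receptor targets upwards too, with 1 of 5 past the threshold, the quinone reductase gene Nqo1 (1.30 ± 0.14, adjusted p = 0.0149; camera adjusted p = 0.018, and adjusted p = 0.329 with an estimated correlation). It called ribosomal proteins (median -0.25, 0 past and 0 adjusted over the list alone), mast cell markers (-0.47, 0 past and 6 lower adjusted over the list alone) and the Notch list (-0.11, 0 past and 2 lower adjusted over the list alone) downwards. Their adjusted p was 3.6e-10, 9.53e-06 and 0.0445, and adjusted p = 0.329 with an estimated correlation in each. Of the small macrophage and dendritic cell markers Ly6c2 rose and Cd209a fell, with 12 of 14 not past the threshold (2 rose and 4 fell adjusted over the list alone). Fcer2a (-1.26, adjusted p = 0.0465) was the only B cell marker past it (1 adjusted over the list alone). None of 12 Chrna7 neighbours passed (Mef2a lowest, -0.76, adjusted p = 0.128; 1 lower adjusted over the list alone). Nor did any of 4 tested sex-linked genes (Kdm5d -0.21 and Ddx3y -0.26; 0 adjusted over the list alone), 9 T and NK cell markers (0 adjusted over the list alone) or 5 granulocyte markers (1 higher adjusted over the list alone).

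No gene passed the LPS by genotype interaction (limma, 0 genes, smallest adjusted p = 0.196, 955 genes at an unadjusted p under 0.05). The response to LPS differed between genotypes by -0.04 ± 0.94 for Il6 (adjusted p = 0.992), -1.62 ± 1.47 for Il1b (adjusted p = 0.729), -0.87 ± 0.60 for Tnf (adjusted p = 0.666), 0.86 ± 0.25 for Nos2 (adjusted p = 0.541) and 0.91 ± 0.29 for Il10 (adjusted p = 0.541). With a pseudocount of 0.1 the number of genes was 1 and Nos2 turned to -0.96, while Il6 turned to 0.73 with a pseudocount of 5 and to 0.15 with quantile scaling. Effects of genotype with and without LPS came from the same model and were chosen after the data were seen. They passed for 133 genes without LPS, 92 of them higher, and 47 with LPS, 36 of them higher. These counts moved with the processing, to 229 and 228 with a pseudocount of 5, 548 and 483 with 0.1, 245 and 144 centred and 119 and 30 with quantile scaling. The count with LPS was the lower one in each of these settings, by 1 gene with a pseudocount of 5, and a difference between the counts was not tested.

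Knockout and wild type libraries of the same treatment were also compared in single pairs, without a test. With vehicle, 333 genes were higher and 207 lower by at least 2-fold in knockout cells, of 7715. The genes that were higher included Ly6i (log2 ratio 5.64), Ly6c2 (26.2-fold), Il1b (22.9-fold), the formyl peptide receptor gene Fpr2 (19.3-fold), Lcn2 (18.5-fold), the chemokine genes Ccl5 (16.6-fold) and Cxcl3 (13.2-fold) and the itaconate-producing enzyme gene Irg1 (12.7-fold). The median of 9 cytokines compared was higher by 2.07, the median interferon-stimulated gene by 1.94, with 28 of 31 higher by at least 2-fold, and the median of 18 chemokines by 1.48, each at percentile 100. Members under 5 FPKM in both libraries are left out there, and over all tested members the medians were 0.58, 1.57 and 1.08 in the same order. With nicotine, 197 genes were higher and 177 lower of 7262, Lcn2 (32.0-fold), the protease gene Mmp14 (11.5-fold) and Irf7 (11-fold) among the highest, and the cytokine, chemokine and interferon-stimulated medians were 0.72, 0.71 and 1.78 over 10, 17 and 20 members compared, and 0.23, 0.76 and 1.18 over all tested members. With LPS, 365 were higher and 156 lower of 7322. Il17a (28.0-fold), Ifnb1, encoding interferon β (23.0-fold), Il17f (20.9-fold), Ccl12 (10.3-fold), the arginase gene Arg1 (9.61-fold) and the interleukin 23 receptor gene Il23r (9.33-fold) were higher in knockout cells, and Csf2 (24.1-fold), Plet1 (12.8-fold) and Mmd (11.2-fold) lower. The median interferon-stimulated gene then differed by 0.40. With nicotine and LPS, 337 were higher and 175 lower of 7216, among them Lcn2 (33.2-fold higher), Il1b (16.8-fold higher), Serpina3f (15.7-fold higher) and Cd244 (12-fold lower), and the median interferon-stimulated gene was higher by 1.67.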

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

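The checks of carry-over between libraries, of a single stimulated culture, of other cell types and of Chrna7 as a control of the labels, and the counts over other splits of the libraries, were chosen only after the results were seen. The tests of gene length, GC content and the chromosome 7 segment were written down before.

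The nicotine effect differed with and without LPS in 3219 genes by the limma test of the interaction, with 1 residual degree of freedom, and 0 passed without the filter on FPKM. In simulated data with the spread of the real fit, 29.0% of the calls of this test were false. Far fewer genes were changed there (100 by 2-fold and 100 by 4-fold), so this share does not carry over to the real calls. Of the 3219 genes, 447 had nicotine effects past the threshold in opposite directions. Of these, 218 were higher without and lower with LPS, and 229 the reverse. Rises with nicotine under LPS can rest on low values. Of the 1339 positive interaction calls, 893 were under 5 FPKM in both libraries given LPS alone. So were all the positive genes named next except Nfam1. The named genes with opposite effects, given as the nicotine effect with LPS minus that without, included Il1a (-6.18), Osm (-5.67) and Lipg (-5.11), and in the other direction Sesn1 (4.20), Ypel3 (4.06), Dbp (3.88), Susd3 (3.85), Rgs2 (3.64), Mxd4 (3.37), Nfam1 (3.30), Kcnj2 (3.29) and Lair1 (3.29).

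The nicotine changes of the genotypes resembled each other, with a correlation across genes of 0.930. Removing each library's trend on transcript length left this correlation at 0.930 (0.931 before, 10042 genes) and the number of nicotine genes at 4583 (4634 before, 4224 shared), and removing the trend on GC content left it at 0.931 with 4643 genes before and after (4384 shared), so the tables argue against these biases as its source. Chrna7 was at 0 FPKM in all 8 libraries, a value that cannot show whether the knockout libraries came from knockout cells, so mislabelled or wild type cells cannot be told apart from a true knockout. What the knockout changes stays open for the same reason and was not tested apart from the labels. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as 4842 genes (highest other 352, the split by LPS), the smallest share that 35 splits allow; the 29 splits that follow no factor gave 0 and leave the real nicotine effect in their spread, so this count does not settle chance.

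In single pairs without a test, knockout values lay above wild type with vehicle. The median was 1.94 over 31 interferon-stimulated genes and 2.07 over 9 cytokines with at least 5 FPKM in either library. Over all 36 and all 22 it was 1.57 and 0.58. Averaged over the treatments, 0 of 36 and 0 of 22 passed for genotype in the additive model. The LPS by nicotine difference, negative in 19 and 18 of them, enlarges the spread of that test. Carry-over of reads from the LPS libraries is argued against: with the carried share bounded at 0.0297% by Il6, 97.9% of 48 raised members of these lists and the chemokines (47) lay above the level it could bring by more than a factor of 2. That only the knockout vehicle culture was stimulated is argued against for the interferon-stimulated genes, whose median between the nicotine libraries of the genotypes, which leave that culture out, was 1.78 over 20 members (18 higher) and 1.18 over all 36. For the cytokines it was 0.72 over 10 members (7 higher, percentile 100 of random lists) and 0.23 over all 22, of which 12 were under 5 FPKM in both libraries, and for the chemokines 0.71 over 17 (14 higher, percentile 100) and 0.76 over all 22 (18 higher), values that neither exclude such a culture nor show one. The genotype itself, the animals and the preparation of the knockout cells stay open too and were not separated by this design.

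The genotype calls included Vsig4, Cd209a and Ly6i. A segment of chromosome 7 from another strain is argued against as the source of most of these calls. Of 110 calls with a position, 0.909% (1, Mfge8) lay within 20 Mb of Chrna7, against 1.49% of tested genes (Fisher's exact test, two-sided, p = 1). Whether such a segment is present, and strain differences elsewhere in the genome, were not tested and stay open. A gain of B, T and NK, mast cells and granulocytes alike is argued against too. The median genotype change over their 38 markers was -0.11 (95% bootstrap interval -0.30 to 0.02) against -0.32 for the resident macrophage list. By list, the median was -0.47 for mast cells, -0.05 for B cells and 0.03 for T and NK cells. The 5 granulocyte markers had a median of -0.04 and a mean of 0.35. A pooled median cannot exclude a gain of 1 cell type, so more granulocytes, B cells or T and NK cells stay open. A shift towards small or monocyte-derived macrophages and dendritic cells may underlie these genes and stays open, since their 14 markers went both ways (median -0.21, Ly6c2 higher and Cd209a lower, camera adjusted p = 0.373), as does a different state of the macrophages or of the preparation. Of the 35 splits, 4 gave at least 115 genes, the real one and those by nicotine (4550, the highest other), by LPS (2630) and by LPS and nicotine combined (1588), which follow the treatments and point to a structure of the libraries, so this count is no measure of chance for genotype; the 29 splits that follow no factor gave at most 2.

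For LPS 1 of the 35 splits, the real one, gave 2824 genes (highest other 2642, the split by nicotine), and the 29 splits that follow no factor gave 0. They leave the real LPS effect in their spread, so this count does not settle chance either.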

How the results depend on the processing

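The effects within 1 genotype or 1 treatment and their alternatives were chosen only after the data were seen. Of 153 values of counts and list tests under alternatives fixed in advance, 112 stayed within 1.5 times or on their side. Of 5165 for named genes, 4290 kept direction and call, or in pair contrasts moved within a set error, 339 lost the call, 15 gained it and 19 reversed. Another 502, which have no test, moved by more or had no such error. In every pair contrast the error was the SE of the gene's nicotine effect with LPS, so it was not an error of the contrast itself. The cause was not tested where none is given.

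For LPS (2824 genes) the count was 520 with the factor alone, 1442 with matched pairs as a block and 803 to 2335 with 1 library left out (1047, 1311, 803 and 944 without wild type vehicle, wild type LPS, knockout vehicle and knockout LPS). For genotype (115) it was 55 without a filter, 19 alone, 798 in blocks and 13 to 171 (26, 36, 171, 24 without wild type vehicle, nicotine, LPS and nicotine with LPS, and 21, 13, 17, 37 without the knockout libraries in that order). For nicotine (4842) it was 2805 alone and 3675 to 4419. A library left out leaves 1 matched pair incomplete. LPS by nicotine (3219) gave 0 without a filter and otherwise up to 3684, and the cause was not tested; LPS by genotype (0) gave 1 with a pseudocount of 0.1. With an estimated correlation 0, 0 and 0 lists were called for LPS, genotype and nicotine, and fry called 5 for genotype.

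Reversed values were, for LPS, Hmox1 -0.13 (quantile). With 1 library left out, genotype values ranged from -0.38 (wild type vehicle) to 0.88 for Tnf, -0.28 (wild type vehicle) to 0.63 for Jak2 and -0.73 to 0.18 (wild type nicotine with LPS) for Dcn. Nicotine values ranged from -0.18 (wild type vehicle) to 1.00 for Tnf, -0.23 (wild type nicotine) to 1.13 for Cd69, -0.049 (knockout vehicle) to 0.25 for Hsp90b1 and -0.35 to 0.0054 (wild type LPS) for Xbp1. Stat3 ranged from -0.57 to 0.17 (wild type nicotine with LPS; 0.168 without knockout LPS, 0.0015 without wild type LPS). For LPS by genotype they were Nos2 -0.96 (pseudocount 0.1) and Il6 0.73 (pseudocount 5) and 0.15 (quantile), for genotype by nicotine Il6 -0.63 and Hes1 0.23 (0.1) and Il10 0.00698 (5), and for LPS by nicotine Il10 0.42 and Hes1 0.0142 (5). With quantile scaling Xbp1 without LPS was -0.15 and Tnf with LPS 0.058. Genotype without LPS (133) gave 245 centred and 229 and 548 with pseudocounts of 5 and 0.1, and with LPS (47) 30 (quantile), 144, 228 and 483.

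At least 20 FPKM in pairs, which compares fewer genes, gave 1688, 1464 and 1939 in wild type (nicotine with LPS over LPS, nicotine, LPS), 1547, 1368 and 1627 in knockout, and 325, 212, 329 and 315 for knockout over wild type (vehicle, nicotine, LPS, both). A pseudocount of 5 gave 1555 and 1434 for nicotine over vehicle and 359, 211, 340 and 323 for knockout over wild type. The difference of nicotine effects under LPS (486) became 292 with a pseudocount of 5 and 294 at 20 FPKM. Depth limits low genes most, and no counting error could be set against these values.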

Other observations

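The genes here, and the values singled out, were chosen only after the data were seen, as was the repeat of the elongation test across genotypes, while that test itself was written down before its result. Each value is 1 library.

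Il17a was at 54.9 FPKM in knockout and 0.996 FPKM in wild type cells with LPS, Il17f at 50.8 and 1.48, and Il23r, the receptor gene for interleukin 23, at 12.2 and 0.417. The 4 T and NK cell markers compared between these libraries had a median log2 ratio of 0.74 (1 higher by at least 2-fold, percentile 99.1 of random lists). With nicotine before LPS the knockout values of Il17a, Il17f and Il23r were 9.31, 12.4 and 1.03. Ifnb1 was at 165 FPKM with LPS in knockout against 6.21 in wild type cells, and 134 and 20.6 with nicotine and LPS. Csf2 went the other way, with 604 FPKM in wild type and 24.1 FPKM in knockout cells with LPS, and 0.607 and 3.05 with nicotine before LPS. Among receptors for acetylcholine, the nicotinic subunit gene Chrnb2 had 0.312 FPKM with vehicle and 1.14 FPKM with nicotine in wild type and 0.229 and 0.381 in knockout cells, and the muscarinic receptor gene Chrm3 went from 0.0520 to 1.28 and from 0.0669 to 0.627. Both genes had a mean under 1 FPKM and were not tested, and such low values can be failed estimates.

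The mast cell protease genes Tpsb2 and Cma1 were listed above 0 in all 8 libraries, with higher values with nicotine in both genotypes. Tpsb2 had 80.6, 148, 103 and 293 FPKM in wild type with vehicle, nicotine, LPS and both, and 59.4, 113, 75.1 and 205 FPKM in knockout cells, and Cma1 65.3, 115, 91.8 and 219, and 49.1, 92.0, 68.5 and 180. The tryptase gene Tpsab1 did not follow them, with 8.62, 7.85, 17.6 and 12.1 FPKM in wild type and 5.43, 6.12, 12.1 and 7.82 FPKM in knockout cells. Kit, the stem cell factor receptor of mast cells, had 4.58, 3.78, 4.07 and 6.23, and 3.12, 3.35, 2.91 and 5.89. The cytoskeletal gene Actb, often used as a reference, went from 1272 to 491 FPKM with nicotine and from 2879 to 425 FPKM with nicotine under LPS in wild type, and from 1343 to 488 and from 4726 to 537 in knockout cells.

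A hypothesis was that nicotine may lower LPS-induced genes by slowing transcription elongation, which would lower long genes more. Among 685 genes with a position raised at least 4-fold by LPS without nicotine, 596 had a negative nicotine change under LPS, with a median of -1.67. They were chosen on the LPS libraries that this change is measured against, which favours negative values. With genes chosen in 1 genotype and measured in the other, 662 of 775 (wild type, then knockout) and 606 of 710 were negative, against 52.3% and 49.8% of all tested genes. The rank correlation of that change with genomic span was 0.116 (95% bootstrap interval 0.0412 to 0.189), the opposite sign. It was 0.0340 and 0.181 with the choice and the measure in different genotypes, so long genes did not fall more. The size of the LPS rise was not adjusted for, and RNA was taken only at 4 h. Slowed elongation that leaves no such trend can therefore not be excluded. Genes are not independent replicates, and no other explanation of these falls was tested.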
